A study of Mus musculus with 6 samples.

How the data were processed

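Gene expression was measured on 6 Affymetrix mouse genome arrays, each hybridised with biotin-labelled cRNA from 1 sample of total RNA. The samples fell into 4 groups by tissue and genotype: Sin3B-deleted pancreas (n = 2), control pancreas (n = 2), Sin3B-deleted PDEC (1 array) and control PDEC (1 array). PDEC are primary pancreatic duct epithelial cells kept in culture on Matrigel in a medium with dexamethasone. All animals carried the KRas G12D allele on a mixed genetic background, per the labels. The controls are called wild type in the sample titles, while the series description gives them 1 remaining Sin3B allele in the pancreas, and they are called controls here for that reason. The series description speaks of separate pancreata for each genotype, so the pancreas arrays were treated as separate animals.

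The deposited values are log2 expression values made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects the background, normalises the arrays by quantiles and summarises the probes of a probe set into a single log2 value. The table held 45037 probe sets for the 6 arrays. The deposited log2 values are not expression levels. In 100% of probe sets the median of the 4 pancreas arrays was 0 within a tolerance of 1e-05, so each probe set had been centred on its own pancreas median. The PDEC values had been centred on another baseline, which is not given in the sources used here. The 2 PDEC values summed to 0 in 14.4% of probe sets, close to the 16.7% that would follow if these were 2 of 4 arrays centred on their median. The base and scale of the logarithm follow from RMA and are not stated separately. The direction was read as higher for more RNA, which the lower Sin3b values in all 3 Sin3B-deleted arrays bear out. The array medians were 0.03 and 0.04 in the Sin3B-deleted pancreas arrays, −0.06 and −0.04 in the control pancreas arrays, −0.0043 in Sin3B-deleted PDEC and 0.0026 in control PDEC.

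Centring removed the level of each gene. Pancreas could therefore not be compared with PDEC, and neither tissue comparison that had been laid out was run. A filter on dim probe sets, repeated quantile normalisation, a mean-variance trend in the test, random lists matched on expression and the condition on the level of a named gene all need levels and were dropped. The choice of the brightest probe set of each gene needs levels too, so the mean of all probe sets of a gene was used, which had been listed as an alternative. Differences between arrays of the same tissue are unaffected by the centring. Signal over background is unknown for the same reason, and the number of arrays sets the precision.

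Probe sets were named from the platform annotation, in which 34945 had a single gene symbol, 932 had several and 9160 had none. Those with several symbols or none were not named or tested. Of the named probe sets, 34741 matched the current mouse symbol table by Entrez identifier, and 0 symbols needed updating. The tested set held 18193 genes, 9010 of them with more than 1 probe set. The sources used here name no genome build, so no coordinates are given.

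Pancreas groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, 4 arrays, Benjamini-Hochberg adjustment over 18193 genes, threshold 0.05). An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Genes whose groups did not overlap were counted as well, which chance gives in 33.3% of genes when both directions are added. In PDEC, with 1 array for each genotype, no test was made, and genes with a log2 difference of at least 1 were counted. The difference of the genotype effect between pancreas and PDEC was tested with an interaction contrast in a limma fit of all 4 groups. There the single PDEC arrays are assumed to vary like the pancreas arrays.

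A set of 27 gene lists with 453 genes, of which 413 were measured, was chosen from textbook knowledge, and 26 lists were tested with limma's camera at a preset inter-gene correlation of 0.01. The sex-linked list was described only. Calls were also made with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way. With 4 arrays the estimated correlation and its test rest on few residuals, and its power was not simulated. A call lost there does not show that correlation between genes explains it. In PDEC the median of each list was placed among 10000 random lists of the same size. The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The naming rule took, for pancreas, the 10 genes with the largest change in each direction among those past the threshold with no overlap of the groups, filled up by moderated t where too few passed. For PDEC it took the 10 largest differences in each direction, and for each list 2 to 4 members with the largest change together with Il1a, Il1b, Cdkn2a and Cdkn1a.

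Control pancreas 1 stood apart from the other pancreas arrays, so each count was also made without it. Leaving out each array in turn had been planned, and giving the result without this array beside each count was chosen after the data had been seen. In the fit without it the remaining control is assumed to vary like the Sin3B-deleted pancreata. Other alternatives were re-centring each array on its median or its 75th percentile, testing every probe set, leaving out probe sets ending in _x_at, using the probe set with the widest range, robust variance estimation, array weights, all 6 arrays in a single fit, the replicate number as a block, taking Sin3b out of the SIN3-HDAC list, and leaving out each array in turn.

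The scripts were tested on simulated data for 18193 genes with 200 changed genes. With the noise of each gene set to its fitted variance, the comparison of 2 pancreata with 2 recovered 0%, 71.6% and 98.5% of genes changed by 1, 2 and 4 on the log2 scale, and 8.87% of the calls were false. The same comparison lacking control pancreas 1 recovered 98.5%, 100% and 100% of these sizes, and 22.0% of the calls were false. With variances drawn from the fitted distribution the recovery was 0%, 0% and 71.2% for 2 against 2, with 2.08% false calls, and 16.4%, 98.5% and 100% without control pancreas 1, with 7.14% false calls. In the interaction contrast, genes changed by 4 were recovered in 68.2% and 0% of cases under these noise models, and smaller changes in 0%. Lists without a simulated change gave 0 calls among 26 in camera at the preset correlation. The simulated genes varied independently of each other, so this does not check camera's calls for genes that vary together. In the runs without control pancreas 1, the lone control was drawn with the variance fitted to the deleted arrays. Over probe sets the SD of the difference was 0.91 between the control pancreata and 0.30 between the deleted ones. The real share of false calls may therefore be higher than simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.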

Results

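The arrays compared pancreas tissue and cultured duct epithelial cells from mice with an activated KRas allele, with and without Sin3B. SIN3B is a scaffold protein of the SIN3-HDAC corepressor complex, which represses transcription by bringing histone deacetylases to promoters. Activated KRas in the pancreas leads to premalignant lesions with inflammation and scarring. The series has 4 pancreas arrays, 2 for each genotype, and 2 PDEC arrays, 1 for each genotype. Each value is a log2 expression value relative to the median of its gene in the pancreas arrays, or to a separate baseline in PDEC, so differences within a tissue can be read and levels cannot.

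Sin3b itself was lower in every Sin3B-deleted sample at 3 of its 5 probe sets. In pancreas the mean difference was −3.35 (SE 0.31) at probe set 1455039_a_at, −2.75 (SE 0.38) at 1434637_x_at and −1.81 (SE 0.34) at 1424355_a_at, with both deleted arrays below both controls. In PDEC the same probe sets differed by −4.02, −3.65 and −3.64, and Sin3b signal at 1455039_a_at was 16.2-fold lower in the deleted culture. At 1425630_at the differences were 0.54 in pancreas and 0.05 in PDEC, and at 1452849_at they were −0.28 and −0.32. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here. None of the 5 passed limma's threshold in pancreas, where the adjusted p at 1455039_a_at was 0.396, and without control pancreas 1 it was 0.00525. Averaged over its 5 probe sets, Sin3b differed by −1.53 (SE 0.24) in pancreas and by −2.31 in PDEC.

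**Figure D1:**
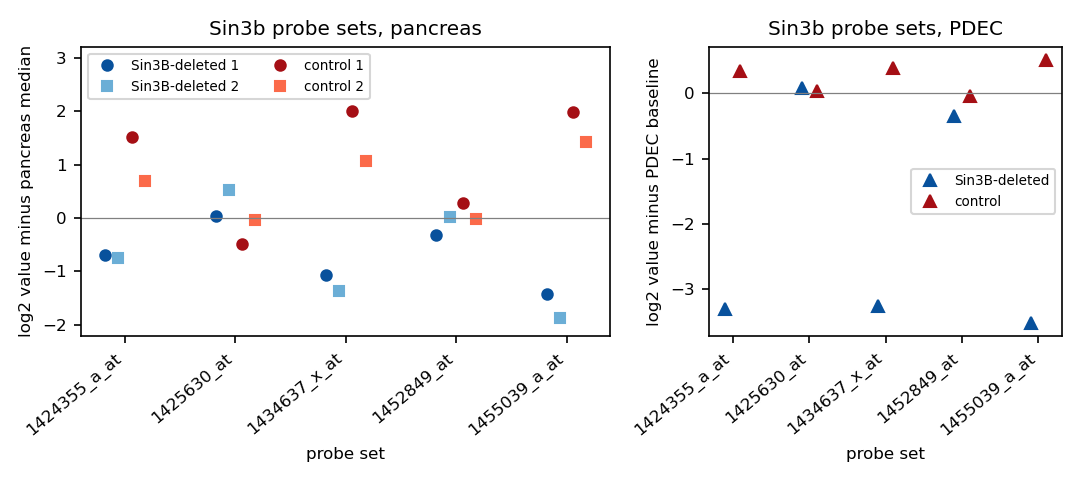
Log2 values of the 5 Sin3b probe sets in each pancreas array (left, relative to the pancreas median) and each PDEC array (right, relative to the PDEC baseline); each point is 1 array. At 3 probe sets the Sin3B-deleted arrays lie below the controls, by −3.35 in pancreas and −4.02 in PDEC at 1455039_a_at.

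The pancreas comparison asked which genes depend on Sin3B in a pancreas with activated KRas. Haptoglobin (Hp), an acute-phase plasma protein, had the largest moderated statistic, with a difference between genotypes of −5.19 on the log2 scale (SE 0.25, 2 against 2 arrays), a 36.5-fold lower signal in Sin3B-deleted pancreas. Next to it stood genes of macrophages and of the immune response, with lower values in both deleted arrays than in both controls, as the naming rule required. They were the complement protease gene C1s1 (−2.94, SE 0.21), the chemokine gene Ccl8 (−3.56, SE 0.26), the macrophage genes Clec4a3 (−3.16, SE 0.23), Aif1 (−2.78, SE 0.23) and F13a1 (−2.56, SE 0.21), and the interferon-induced GTPase gene Gbp3 (−2.31, SE 0.18). Vegfd, a growth factor for lymphatic vessels, differed by −2.92 (SE 0.19), the enkephalin precursor gene Penk by −2.83 (SE 0.23) and the fibrillar collagen gene Col3a1 by −3.03 (SE 0.25). In the other direction the largest moderated statistics belonged to Arg2, the mitochondrial arginase (2.12, SE 0.24), the sodium channel subunit gene Scn4b (1.88, SE 0.27) and the lipid kinase gene Pik3c2g (1.76, SE 0.26). Klra5, Fam222a, Rmdn3, Gm33560, Tekt4, AU015836 and Lect2 followed, with differences from 1.07 (AU015836) to 1.20 (Gm33560).

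None of these differences passed the test over all genes. limma called 0 of 18193 genes, with a smallest adjusted p of 0.254, while 1997 genes had an unadjusted p under 0.05, 689 of them higher and 1308 lower in Sin3B-deleted pancreas. Groups did not overlap for 6889 genes that were higher (37.9%) and 4578 that were lower (25.2%), against 33.3% by chance for both directions together, and 1986 of these genes differed by at least 1, 365 higher and 1621 lower. The chance share assumes no offset between arrays, while the median difference of all genes was 0.08, and the count was not repeated after re-centring. All genes share the same 4 arrays, so the excess over chance does not show how many genes changed with genotype. The result turned on the control arrays: limma called 690 genes without control pancreas 1, 29 higher and 661 lower, and 10196 genes without control pancreas 2, 4786 higher and 5410 lower. In the fit lacking control pancreas 1, Hp differed by −4.96, Arg2 by 2.02 and Col3a1 by −2.96. The 20 genes named above had been picked from the same arrays, so that fit is no independent check of them. Its spread came from the 2 deleted arrays alone, so its calls may hold more false ones than the threshold allows.

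**Figure D2:**
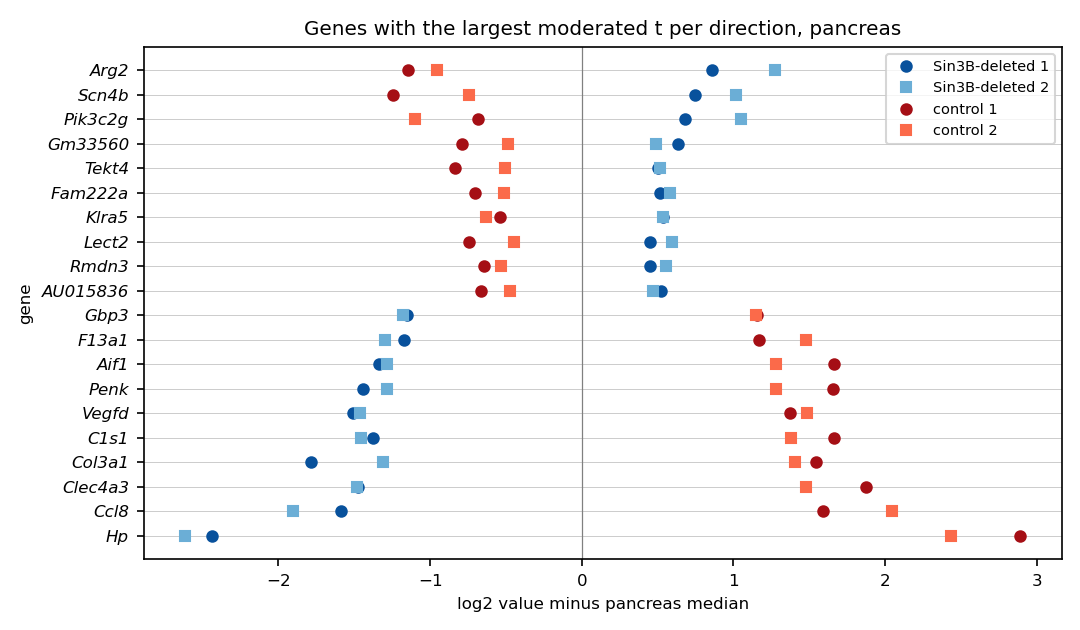
Log2 value relative to the pancreas median (horizontal axis) of the 20 genes with the largest moderated statistics (vertical axis), 1 point for each pancreas array. Both Sin3B-deleted arrays lie on the same side of both controls for every gene, and Hp has the widest difference, −5.19.

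Control pancreas 1 stood apart from the other pancreas arrays. In it 20.4% of probe sets lay at least 1 from the pancreas median, against 1.54% and 1.61% in the Sin3B-deleted arrays and 1.03% in control pancreas 2. Its acinar enzyme genes, which encode the digestive enzymes that make up most of the RNA of a normal pancreas, had a median of −8.47, and all 22 measured members lay below −4. The same list had medians of 0.01, 0.01 and 0.01 in the other arrays. Its Xist value was 6.04, while the other pancreas arrays lay between −0.22 and 0.06.

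Macrophage and monocyte genes were lower in Sin3B-deleted pancreas as a group, with a median difference of −3.14 over 22 measured members. All 22 were lower in both deleted arrays than in both controls, 0 passed over all genes and 19 passed when adjusted over the list alone. Chil3, a chitinase-like protein of alternatively activated macrophages, differed by −5.89 (SE 2.72), the protease gene Ctss by −3.98 (SE 0.59), the mannose receptor gene Mrc1 by −3.97 (SE 0.76) and Arg1 by −3.93 (SE 1.74). camera ranked the list below the other genes (adjusted p = 9.34e-18), a call lost at adjusted p = 0.418 with an estimated correlation. The median was −2.06 without control pancreas 1, and 21 members passed limma's test over all genes, while Chil3 then differed by −1.91 and Arg1 by −1.39. What remained there was set against control pancreas 2, whose adipocyte genes had a median of 1.19, against −0.64 in control pancreas 1 and 0.03 and −0.13 in the deleted arrays.

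Fibroblast and matrix genes followed the same course, with a median of −2.77 over 24 members, 23 of them lower without overlap, 0 passing over all genes and 22 adjusted over the list alone. The matrix protein gene Postn differed by −4.06 (SE 0.69), Col1a1 by −3.92 (SE 0.55), Fn1 by −3.88 (SE 1.08) and Bgn by −3.87 (SE 0.75), while the muscle filament gene Des had 0.24 (SE 0.20). camera gave an adjusted p of 1.69e-16, against adjusted p = 0.418 with an estimated correlation. The median was −1.89 without control pancreas 1, and 20 members passed, with Fn1 at −2.31.

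Genes that inflammatory signalling can raise were lower too. Whole tissue was measured, so a change in the cells present cannot be told apart from a change in signalling within them. That holds for these lists and for the RAS-MAPK, immediate-early and inhibitor lists below. Of 15 NF-kB targets, 12 were lower without overlap, with a median of −1.29, 0 passed over all genes and 9 adjusted over the list alone, among them the adhesion molecule gene Icam1 (−2.92, SE 0.56) and the chemokine gene Cxcl16 (−2.13, SE 0.63). camera's adjusted p was 4.89e-08, and adjusted p = 0.418 with an estimated correlation. The senescence-associated secretory factors had a median of −0.80 over 29 members, 18 of them lower without overlap, 0 passing over all genes and 5 adjusted over the list alone. Within that list Timp1 differed by −4.73 (SE 0.87), Mmp12 by −4.55 (SE 1.24), Igfbp3 by −3.86 (SE 0.79) and Ccl8 by −3.56 (SE 0.26), and camera gave adjusted p = 2.9e-06, lost at adjusted p = 0.418 with an estimated correlation. The interleukin-1 pathway had a median of −0.80 over 17 members, 11 of them lower without overlap. There the alarmin gene Il33 differed by −3.84 (SE 0.42) and was the only member to pass when adjusted over the list alone, while the cytokine genes Il1a and Il1b had −0.56 (SE 0.35) and −0.52 (SE 0.26), and camera gave adjusted p = 0.000336, with adjusted p = 0.488 with an estimated correlation. Il1a differed by −0.14 and Il1b by −0.30 without control pancreas 1, and the medians of the secretory and interleukin-1 lists were −0.30 and −0.30. In the same fit Cxcl16 had −1.25 and Mmp12 −2.76.

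Of the genes that report on RAS-MAPK signalling, 14 of 19 were lower without overlap and 8 passed when adjusted over the list alone, against 0 over all genes, with a median of −1.41. The largest differences were those of Ier3 (−4.44, SE 1.02), Egr1 (−3.83, SE 0.42), Fos (−3.59, SE 0.33) and the adaptor gene Phlda1 (−2.92, SE 0.57). camera gave adjusted p = 4.89e-08, and adjusted p = 0.418 with an estimated correlation. The median was −0.72 without control pancreas 1, and 6 members passed. The immediate-early and heat shock list had a median of −1.37 over 12 members, 9 of them lower without overlap, with 6 adjusted over the list alone and 0 over all genes. It was led by the phosphatase gene Dusp1 (−3.43, SE 0.33), the heat shock gene Hspa1b (−3.00, SE 0.53) and Junb (−3.00, SE 0.30), with adjusted p = 7.26e-07 in camera and adjusted p = 0.418 with an estimated correlation.

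The list of senescence genes and cell-cycle inhibitors had 13 of 15 members lower without overlap, with a median of −0.95 and 0 passing either over all genes or adjusted over the list alone. It also holds genes that are not cell-cycle inhibitors, among them Lmnb1, Hmga2 and Mdm2, so the median does not stand for the inhibitors alone. Cdkn2b differed by −4.01 (SE 0.94), Gadd45a by −3.78 (SE 1.19), Cdkn2a, which encodes p16 and p19ARF, by −2.81 (SE 1.19) and Cdkn1a, which encodes p21, by −1.90 (SE 0.60). Cdkn2b differed by −2.66, Gadd45a by −2.05, Cdkn2a by −1.09 and Cdkn1a by −1.06 without control pancreas 1, and the list's median was −0.80. camera gave adjusted p = 1.85e-06, and adjusted p = 0.418 with an estimated correlation. Proliferation genes driven by E2F were lower without overlap in 21 of 33 members and higher in 5, with a median of −0.37 and 0 passing over all genes or adjusted over the list alone. Mki67 differed by −1.82 (SE 0.51, and −1.14 without control pancreas 1), the replicative helicase gene Mcm4 by −1.80 (SE 0.35) and Birc5 by −1.65 (SE 0.25), with adjusted p = 3.15e-05 in camera and adjusted p = 0.418 with an estimated correlation.

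The duct and metaplasia lists were lower in Sin3B-deleted pancreas as well. Duct epithelium had a median of −1.14, with 13 of 18 members lower without overlap, led by the tight junction gene Cldn4 (−3.95, SE 1.13) and the keratin genes Krt7 (−3.79, SE 0.79) and Krt19 (−2.49, SE 0.79), and with 0 passing over all genes or adjusted over the list alone. The list of metaplasia and gastric mucin genes had a median of −1.13 over 17 members, 8 of them lower and 2 higher without overlap, with 2 adjusted over the list alone, Gkn3 (−2.66, SE 0.25) and the protease gene Ctse (−2.26, SE 0.38), and 0 over all genes. The widest difference there was that of the protease gene Mmp7 (−3.04, SE 1.19). camera's adjusted p was 1.03e-05 for the duct list (adjusted p = 0.418 with an estimated correlation) and 0.00225 for the metaplasia list (adjusted p = 0.451 with an estimated correlation). Without control pancreas 1 the medians were −0.61 and −0.05, and Cldn4 had −2.31, Krt19 −1.36 and Mmp7 −1.31.

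Among the remaining cell types, the antigen presentation genes of MHC class II had a median of −1.82 over 7 members, with H2-Ab1 at −3.18 (SE 0.39) and Cd74 at −2.86 (SE 0.38). The median was −0.88 for 14 endothelial genes, led by Vwf (−2.54, SE 0.40), −1.03 for 7 mesothelial genes, led by Msln (−2.24, SE 0.72), and −0.65 for 10 neutrophil genes, led by the iron-binding protein gene Lcn2 (−4.23, SE 1.07) and the calprotectin gene S100a8 (−3.19, SE 0.88). Interferon response genes had −0.40 over 13 members, led by Gbp2 (−2.41, SE 0.32), and SIN3-HDAC complex genes −0.17 over 23 members, led by Hdac1 (−1.79, SE 0.43) and by Sin3b, which the genotype itself lowers. Leaving out control pancreas 1 brought the MHC class II median to −0.66, the interferon response median to −0.82, Msln to −1.23 and Lcn2 to −2.78. The members that passed when adjusted over the list alone numbered 3 in MHC class II, 3 in endothelium, 3 in mesothelium, 4 in interferon response and 0 in the neutrophil and SIN3-HDAC lists, against 0 over all genes in each. camera's adjusted p was 0.00125 for MHC class II, 1.16e-06 for endothelium, 0.0105 for mesothelium, 0.00297 for neutrophils, 0.0115 for interferon response and 0.0061 for the SIN3-HDAC list. These calls were lost as well, at adjusted p = 0.418 with an estimated correlation for the first 4, 0.522 for interferon response and 0.493 for the SIN3-HDAC list. With Sin3b taken out, the SIN3-HDAC list had a median of −0.16 over 22 members and camera's adjusted p was 0.0167, against adjusted p = 0.522 with an estimated correlation. These members had a median of −0.06 when control pancreas 1 was left out as well, with adjusted p = 0.0382 in camera and adjusted p = 0.335 with an estimated correlation. In camera the calls of interferon response and mesothelium were also lost without control pancreas 2, at adjusted p = 0.942 and 0.205. With the widest-range probe set of each gene interferon response was lost too (camera adjusted p = 0.0582), and the interferon response genes had a median of 0.55 in that array and −0.11 in the other control.

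Acinar enzyme genes had a median difference of 4.24 between genotypes, and this came from control pancreas 1. Without that array the median was 0.00 and camera's adjusted p went from 0.000672 to 0.989. With all arrays it was adjusted p = 0.548 with an estimated correlation. Rnase1 differed by 5.26 (SE 3.55) and Cela2a by 5.21 (SE 3.57), and by 0.05 and −0.03 without that array. Acinar regulators had a median of 1.33 over 10 members, with the transcription factor gene Ptf1a at 3.32 (SE 1.90) and the receptor gene Cckar at 4.56 (SE 2.96), and a median of 0.35, with these genes at 0.54 and 0.23, without control pancreas 1. camera gave adjusted p = 0.0174 with all arrays and 0.0237 without that array, lost at adjusted p = 0.522 and 0.325 with an estimated correlation. Unfolded protein response genes had a median of 0.78 over 13 members, led by Chac1 (2.95, SE 1.25). With all arrays camera gave adjusted p = 0.0212, and adjusted p = 0.485 with an estimated correlation. Without control pancreas 1 the median of this list was 0.21, with Chac1 at 1.14. Erythroid genes had 1.23 over 4 members, led by the haem synthesis gene Alas2 (2.13, SE 0.80), with adjusted p = 0.0193 in camera, lost at 0.0834 without control pancreas 1, at 0.103 without control pancreas 2 and at adjusted p = 0.418 with an estimated correlation. In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

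The lists that did not pass in camera were the Reg family (median 2.93, adjusted p = 0.128), islet endocrine genes (−0.09, adjusted p = 0.206), T and NK cell genes (0.10, adjusted p = 0.404), B and plasma cell genes (−0.20, adjusted p = 0.182) and adipocyte genes (−0.29, adjusted p = 0.146). Again 0 members passed in each, over all genes or adjusted over the list alone. Reg3a differed by 4.23 (SE 3.37), Chgb by −2.26 (SE 0.66), Cd4 by 0.92 (SE 0.34), Jchain by −4.82 (SE 1.24) and the adipokine gene Adipoq by −3.45 (SE 1.90). Without control pancreas 1 the Reg family turned to a median of −0.33 (camera adjusted p = 0.00777), islet genes had −0.35 (0.00863), T and NK cell genes 0.06 (0.983), B and plasma cell genes −0.11 (0.0121) and adipocyte genes −1.19 (1.97e-10). The calls of the Reg, islet, B and plasma cell and adipocyte lists were lost at adjusted p = 0.391, 0.532, 0.302 and 0.302 with an estimated correlation, and the single genes had −0.72 for Reg3a, −1.34 for Chgb, 0.50 for Cd4 and −6.23 for Adipoq. Re-centring the arrays on their 75th percentile moved the median of all genes by 0.12, from 0.08 to 0.20, and on that scale the islet median was 0.03. In total 21 of 26 lists passed with the preset correlation, 17 lower and 4 higher, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.198. fry gave an unadjusted p of 0.0366 for the macrophage list. The test with an estimated correlation rests on few residuals and its power was not simulated, so its 0 calls leave open whether a list changed.

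**Figure D3:**
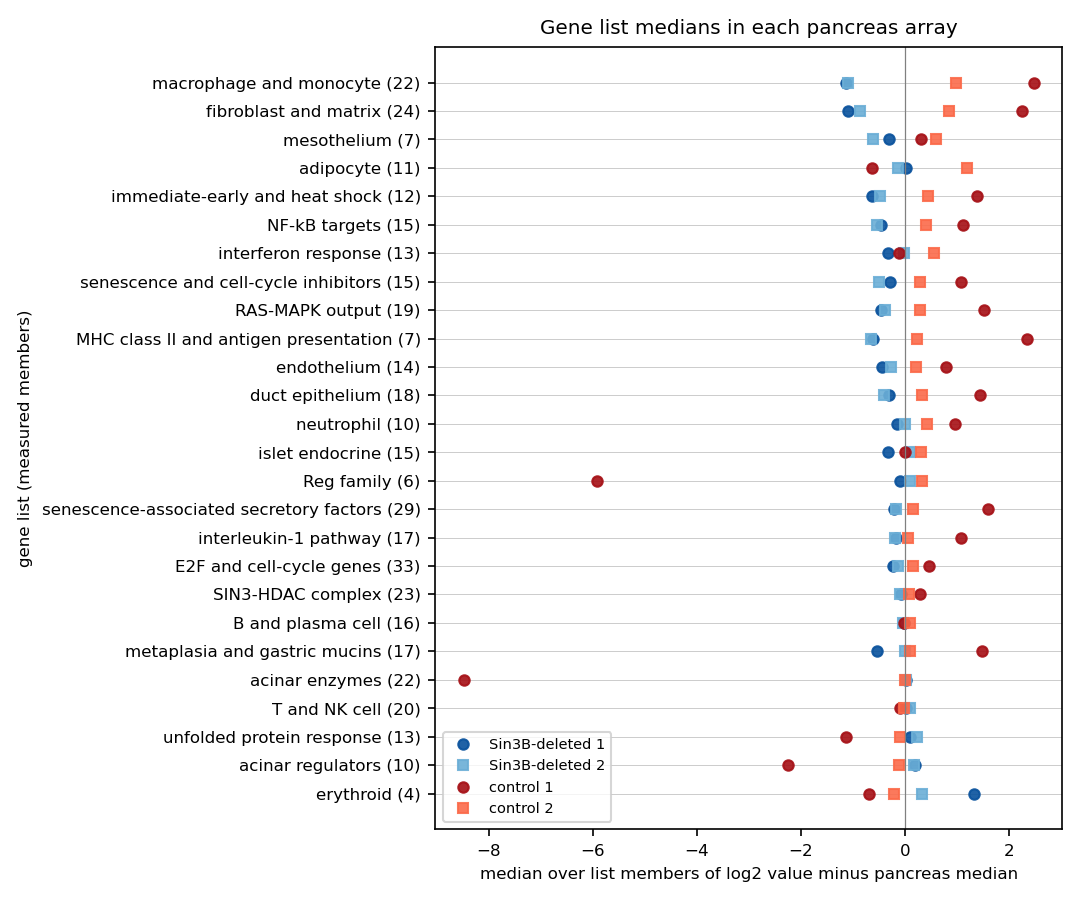
Median log2 value relative to the pancreas median (horizontal axis) of each tested gene list (vertical axis, number of measured members in brackets), 1 point for each pancreas array. Control pancreas 1 has the acinar enzyme list at −8.47, and the macrophage list lies at −1.14 and −1.09 in the Sin3B-deleted arrays against 2.47 and 0.98 in the controls.

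In PDEC the comparison asked what differs in the duct epithelial cells themselves. Only 1 array stands for each genotype, so differences have no replicate check and no p-value. Between the 2 cultures 183 genes (1.01%) differed by at least 1, 77 higher and 106 lower in the Sin3B-deleted culture. The widest difference was that of Xist, the RNA that silences an X chromosome in female cells, at 7.56. After it came the proteoglycan core gene Srgn (4.25), Obp2a (3.96), the apolipoprotein gene Apoc1 (3.52), the interferon-induced membrane protein gene Ifitm3 (3.33), 4732490B19Rik (3.24), Apoe (2.95), Gatm (2.71), Serpina1c (2.65) and the glucose transporter gene Slc2a3 (2.47). Lower in the Sin3B-deleted culture were the apolipoprotein gene Apoa1 (−4.23), the Y-linked gene Eif2s3y (−3.75), the alcohol dehydrogenase gene Adh1 (−3.32), Ap1s3 (−3.02), Prl7b1 (−2.95), Havcr2 (−2.75), Zic5 (−2.69), Dnase1l2 (−2.68), the Y-linked gene Uty (−2.34) and Agmo (−2.34). In the sex-linked list Kdm5d, also on the Y chromosome, differed by −1.75, so the 2 cultures differed in sex-linked genes as well as in genotype.

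**Figure D4:**
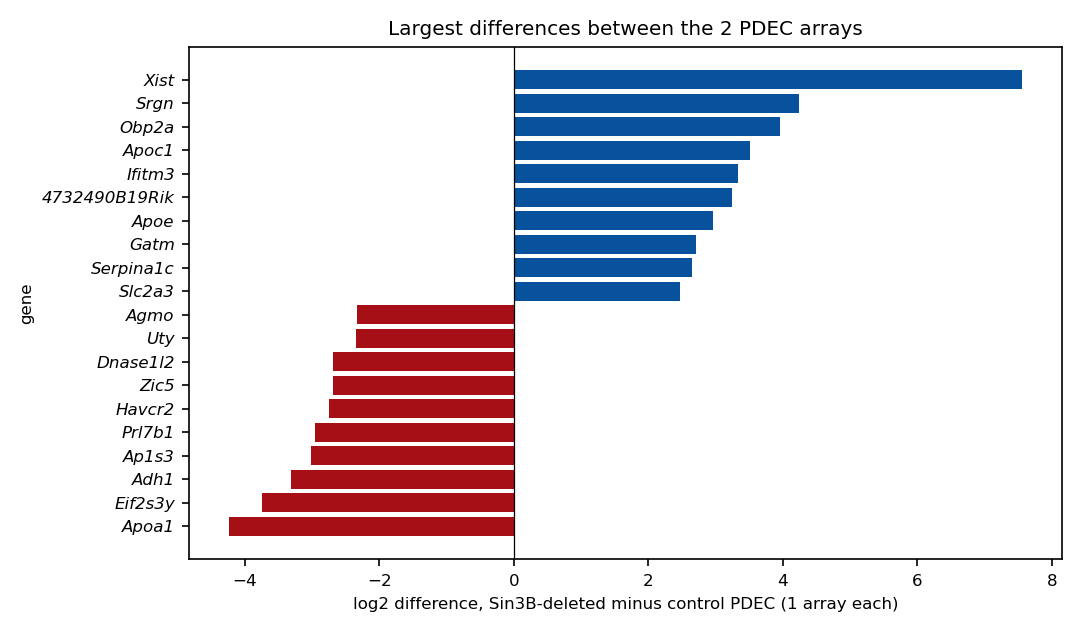
Log2 difference between the Sin3B-deleted and the control PDEC array (horizontal axis) for the 10 genes with the largest difference in each direction (vertical axis). Bars start at 0 and run from −4.23 for Apoa1 to 7.56 for Xist, with 1 array for each genotype.

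Most gene lists lay within the central 95% of random lists in PDEC, and 6 lay outside. Above it were acinar enzymes, with a median of 0.33 and Cela2a at 2.02, and B and plasma cell genes, with a median of 0.14. The B and plasma cell list lay within it, at 0.09 and percentile 90.5, when the widest-range probe set of each gene was used. Below it were unfolded protein response genes (−0.32), mesothelial genes (−0.21), immediate-early and heat shock genes (−0.20) and senescence and cell-cycle inhibitors (−0.12). In the unfolded protein response list Ddit3 differed by −0.80, among immediate-early genes Egr3 by −0.96 and Atf3 by −0.92, and among the inhibitors Cdkn2a by 0.66 and Cdkn1a by −0.12. The macrophage list had a median of 0.01, at percentile 60.9, and the fibroblast list 0.04, at percentile 78.2. Interleukin-1 pathway genes had −0.06, with Il1a at −0.72 and Il1b at 0.27, and the secretory factors −0.02, with the chemokine gene Cxcl2 at −2.29. The neutrophil list had a median of 0.06, at percentile 78.6, with 6 of 10 members above 0, while Lcn2 differed by −1.79 and S100a9 by −1.36.

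Whether the genotype difference was the same in pancreas and PDEC was tested with the interaction contrast. Hp differed by −5.19 in pancreas and −0.95 in PDEC, and Col3a1 by −3.03 and −0.02. Srgn and Apoe were higher in Sin3B-deleted PDEC and had −3.52 (SE 0.86) and −3.64 (SE 0.66) in pancreas, or −2.30 and −2.75 without control pancreas 1, and Arg2 went from 2.12 in pancreas to −1.21 in PDEC. limma called 0 of 18193 genes for this difference, with a smallest adjusted p of 0.914 and 446 genes at an unadjusted p under 0.05, so the effects are not shown to differ for any of these genes. Without control pancreas 1 it called 190 genes, 23 with a more positive and 167 with a more negative effect in pancreas, and without control pancreas 2 it called 5118, 1802 and 3316. Across genes the differences in the 2 tissues correlated at r = 0.10 (rho 0.19), from 0.06 to 0.11 over single pairs of pancreas arrays, and 57.3% of genes had the same sign, where genes are not independent replicates. Of the genes at an unadjusted p under 0.05 in pancreas, the sign in PDEC was the same for 62.6% of those that were higher and 57.3% of those that were lower. It was the same for 51.4% of the 661 genes that limma called lower without control pancreas 1 (r = −0.02), and the 183 genes that differed by at least 1 in PDEC had the same sign in pancreas in 54.6% (r = −0.04).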

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

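The tests of the explanations below and the gene lists' tests of a difference between tissues, with all arrays and without control pancreas 1, were chosen after the results had been seen. With the preset correlation, camera gave 20 of 26 lists a genotype effect that differed between pancreas and PDEC, 16 more negative in pancreas and 4 more positive. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.437, and the single PDEC arrays carry no spread of their own. The PDEC medians of the macrophage and fibroblast lists were 0.01 and 0.04, so their difference of effects largely repeats the pancreas difference. Whether the cultured duct cells express such genes at all is unknown. The 2 cultures also differed in sex-linked genes, so the contrast cannot show an effect of Sin3B that depends on tissue.

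The macrophage list had a median difference of effects of −3.00 on the log2 scale, fibroblast and matrix genes had −3.00, MHC class II genes −1.93, RAS-MAPK output −1.35, NF-kB targets −1.23, immediate-early and heat shock genes −1.17 and metaplasia and gastric mucin genes −1.11. Endothelium followed with −0.997, senescence and cell-cycle inhibitors with −0.91, neutrophil genes with −0.90, the senescence-associated secretory factors with −0.90, duct epithelium with −0.89, the interleukin-1 pathway with −0.75, mesothelium with −0.70, interferon response genes with −0.56 and E2F and cell-cycle genes with −0.44. More positive in pancreas were acinar enzymes (3.80), erythroid genes (1.24), acinar regulators (1.17) and unfolded protein response genes (0.99). When control pancreas 1 was left out, 19 of these 20 lists passed, 18 of them with the same sign, and the acinar enzymes turned to −0.33 while the erythroid list was lost (adjusted p = 0.189 in camera). Most medians moved towards 0 there, to −2.10 for macrophages, −1.99 for fibroblast and matrix genes, −0.77 for MHC class II, −0.73 for RAS-MAPK output, −0.65 for NF-kB targets, −0.77 for immediate-early genes and −0.16 for metaplasia. Endothelium had −0.61, the inhibitors −0.48, duct epithelium −0.52, the secretory factors −0.28, the interleukin-1 pathway −0.27, acinar regulators 0.28 and the unfolded protein response 0.59. Mesothelium and interferon response moved away from 0, to −0.97 and −0.76. In that fit 23 lists passed in all, the others being the Reg family, islet, B and plasma cell and adipocyte lists, and 0 passed with an estimated correlation, with a smallest adjusted p of 0.311.

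Macrophage and matrix genes, 46 in all, had a median of −3.01 in Sin3B-deleted pancreas against control. Control pancreas 1 alone is argued against as the source, since the median without it was −2.04 (95% bootstrap interval over genes −2.33 to −1.76), although the control side then rests on control pancreas 2, where the fat cell genes had a median of 1.19. In the arrays at hand the islet genes go against a larger acinar share that dilutes all other cell types alike. The macrophage median lay −1.71 from the islet median without control pancreas 1 (95% bootstrap interval over genes −2.32 to −1.32). That interval measures the spread between genes and not between animals, and 1 control is left, so other pancreata may differ. Whether Sin3B acts within the epithelial cells cannot be told apart from an effect on other cells, since the 46 genes had a median of 0.031 in PDEC with 1 array for each genotype. Fewer macrophages and fibroblasts in the sampled piece of Sin3B-deleted pancreas may account for the pattern, and the genotype, the sampled piece with any fat in it and the stage of disease all stay open as reasons.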

How the results depend on the processing

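Robust variances, array weights, re-centring on the median, the widest-range probe set, re-centring the gene lists on the 75th percentile, taking Sin3b out of its list, the alternatives for the tissue difference and the correlation across genes other than leaving out arrays and the estimated correlation without control pancreas 1 were chosen after seeing the data. Repeated quantile normalisation, the filter on dim probe sets, the mean-variance trend and both tissue comparisons were not run, because centring had removed the levels that they need. Numbers did not pair the pancreas arrays (correlation of deviations 0.03 for equal numbers); with the replicate block limma called 0 genes, camera 22 lists, and Sin3b kept −1.53. Leaving out each array gave 0 to 10196 genes in pancreas, with 690 without control pancreas 1, 10196 without control pancreas 2 and 0 with either deleted array left out. Without a control, the lone control is assumed to vary like the deleted pair, which then alone gives the spread. The count by size and non-overlap was 1986 genes. All other settings gave 0 genes in limma, with 1140 (all 6 arrays) to 2412 (array weights) at an unadjusted p under 0.05, 5082 of 45037 probe sets tested singly, and 508 and 554 without a deleted array. The number of lists was 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation without control pancreas 1, 19 to 23 over the arrays left out, 21 after re-centring on the 75th percentile or without Sin3b, and 20 with the widest-range probe set, where interferon response was lost (0.0582). Over the arrays left out, camera's adjusted p for the Reg family ranged from 8.32e-06 to 0.0267, and the list reversed only without control pancreas 1 (0.00777), whose low values drop out there. PDEC counts went from 183 of 18193 genes (1.01%) to 248 with the widest-range probe set (1.36%) and 491 of 45037 probe sets tested singly (1.09%), and PDEC lists from 6 to 5 with the widest-range probe set, without the B and plasma cells. The tissue difference gave 0 to 5118 genes over the arrays left out, and the correlation across genes 0.0682 to 0.106, or 0.124 with the widest-range probe set. Sin3b, averaged over probe sets, ranged from −1.75 to −1.31 and passed when either control was left out; it differed by −1.53 with all arrays. Array weights were 3.13 for both deleted arrays and 0.32 for both controls, as 2 arrays in a group deviate equally from their mean, and so could not single out an array. Signal over background is unknown.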

Other observations

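The tests of explanations in this part were chosen after the results had been seen, and so were the genes it names, while leaving out each array had been planned. When control pancreas 1 was left out, the genes with the largest differences among those limma called lower in Sin3B-deleted pancreas included Cxcl13, a chemokine that draws B cells (−4.37, adjusted p = 0.0187), the eosinophil ribonuclease gene Ear3 (−4.08, adjusted p = 0.004) and the protease inhibitor gene Timp1 (−3.50, adjusted p = 0.00553). Higher were Tmed11 (1.83, adjusted p = 0.00725) and genes of amino acid metabolism, Chac1 (1.14, adjusted p = 0.0409) and Cth (1.13, adjusted p = 0.0416), each lower still in control pancreas 1. All these genes were picked among those whose groups did not overlap over all 4 pancreas arrays, control pancreas 1 included. In the comparison without that array 2 deleted arrays were set against 1 control, so it also holds what was particular to control pancreas 2. Fat cell genes are such a case: Adipoq was 5.88 above the pancreas median in control pancreas 2 and 0.32 in control pancreas 1, and 7 of 11 adipocyte genes were called lower in limma without control pancreas 1 and 0 with it, where 1 had an unadjusted p under 0.05.

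The acinar enzyme genes, 22 in all, were lower in control pancreas 1 than in the other 3 pancreata. Its mean Sin3b value lay 1.75 above the higher of the deleted arrays, against 1.31 for control pancreas 2. Whole tissue was measured, and control pancreas 1 differed in the genes of several cell types. Sin3b therefore cannot settle whether a Sin3B-deleted pancreas stood under a control label. Lymphoid tissue is argued against, since B and T cell markers lay −0.12 from the median of the other arrays (95% bootstrap interval over genes −0.33 to 0.04). Control pancreas 2 had the control genotype too, and there the enzymes lay −0.0025 from the deleted arrays (95% bootstrap interval over genes −0.04 to 0.01). Transcripts this abundant can saturate an array and hide small differences, and the interval measures the spread between genes and not between animals. The control genotype thus did not lower these genes strongly in every control. With 2 controls, an effect of genotype that varies between animals stays open. A pancreas whose acinar tissue had largely been lost is a possible explanation, and in that array the duct genes had a median of 1.44 and the macrophage genes 2.47. Another piece of tissue at the time of sampling, the sex of the animal (Xist 6.04) and the stage of disease stay open and were not tested.

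Srgn, Apoe and Arg1, genes that macrophages express, were higher in Sin3B-deleted PDEC by 4.25, 2.95 and 1.74. A large share of macrophages in that culture is argued against, since the other 21 genes of the macrophage list had a median difference of 0.0014 (95% bootstrap interval over genes −0.05 to 0.19). A small share cannot be excluded, since signal over background is unknown and each genotype had 1 array. A difference in sex between the cultures could contribute and cannot be told apart from the genotype, since Xist differed by 7.56 and each genotype had 1 culture. The genotype and the history of each culture stay open too.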
